A study of Mus musculus with 4 samples.

How the data were processed

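RNA of primary mouse T cells was measured by paired-end RNA sequencing in 4 libraries, each deposited as a table with 1 row per gene. The values are counts deposited by the authors: per the file headers, featureCounts 1.4.6-p4 counted fragments with both ends aligned over the exons of each gene of the GENCODE vM13 annotation with strand setting 2 (reverse-stranded), and the options that count fragments aligned to several places or overlapping several genes were not switched on. The alignments are named as STAR output and sorted, with settings not given in the sources used here, and the genome build is mm10 per the labels. Counts of genes with near-identical copies, such as histones, ribosomal proteins and predicted genes similar to ribosomal RNA, are therefore uncertain. Text files that only list the other files of each library were not used here.

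All 4 libraries belong to 1 group by their cell type label, and the replicate numbers come from the labels, which call them biological replicates. All carry the same strain-level donor entry, and no label states that they came from separate animals. Values of Xist and Y-linked genes, given below, argue against a single animal as the source of all 4. The number of animals is not known. P-values therefore measure only the spread between these samples, which may be in part technical. Counts of no 2 libraries agreed within sampling noise (chi-square per degree of freedom between 9.67 and 31.0 over the 6 pairs), so all were kept as separate samples. The condition words and the replicate numbers in the alignment names (1 to 4, same as the labels) were read from the headers and used for no grouping. No contrast between groups could be made.

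The design was written on the assumption of RSEM tables with expected counts, TPM and FPKM. As the files hold whole-number counts, TPM and FPKM were computed here from the counts and the exon lengths in the files, and count tests were run on the counts as deposited, without rounding. Gene symbols came from a table of GENCODE vM21 matched by gene identifier without its version: 50376 of 50600 identifiers matched. Totals ran from 47558517 to 273136467 fragments, so that 3 fragments, the number taken as detection floor, correspond to between 0.0379 and 0.214 TPM for a gene with 1 kb of exons. Floors cover counting error only, since PCR copies are not independent molecules.

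For replicate agreement, Pearson's r and Spearman's rho of log2(TPM + 1) were taken for the 6 pairs of libraries. Variation between replicates was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): filterByExpr (minimum count 10) left 12712 genes, TMM factors were 0.998 to 1.002, trended dispersion was estimated with an intercept-only negative binomial model, and each gene's residual deviance was set against a chi-square distribution with 3 degrees of freedom, with Benjamini-Hochberg adjustment at 0.05. In simulated counts for those 12712 genes with 200 genes moved in 1 random library, the test recovered 28.4% of genes moved 1.5-fold, 59.7% moved 2-fold and 92.4% moved 4-fold, and called 2 genes that had not been moved. The simulation held every gene at the trended dispersion, without dispersions of single genes. It therefore does not give the rate of false calls in the real counts, nor the recovery of genes that differ in several libraries. The spread of a gene list is the median residual deviance of its members, placed among 10000 random lists matched on mean expression in 20 bins; lists with under 5 genes past the filter were left out. Of 100 random lists used to check that step over 12712 genes, 5 fell above percentile 95, and a list raised 5-fold was at percentile 100. Levels of 37 gene lists were described by the number of members at 1 and at 10 TPM in all 4 libraries and by the median. The place of that median among 10000 random lists of genes with a symbol, part of the design, is not reported, since most of the draws hold genes without fragments and nearly any list of transcribed genes lies above them. The difference of 25 gene pairs on the log2(TPM + 1) scale was tested within libraries by an exact two-sided sign-flip permutation test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

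The lists, pairs, tests and alternatives were fixed before the data were examined. Genes named in the text are those of the fixed pairs, the 4 members of highest mean TPM in each list (2 for lists of other cell types, any member for the cytokine, Th1, Th2, Th17, regulatory and follicular helper lists), the 10 genes of highest mean TPM outside mitochondrially encoded and ribosomal protein genes, the 10 genes of largest residual deviance past the threshold, and list members past it; Xist and Y-linked genes are given per library. Havcr2, Ece1 and genes named in the closing section outside these parts were chosen after their values were seen. Some genes that these parts would name are not reported here. Alternatives were other minimum levels (0.5 and 2 TPM, 1 FPKM, 10 counts), other pseudocounts, FPKM or log2 CPM in place of TPM, TPM without mitochondrial, ribosomal protein and unnamed rows, size factors of DESeq2 1.42.0, no filter or a mean of at least 50 counts, common dispersion, dispersion outliers of DESeq2 and the omission of each replicate. Thinning replicate 2 at random to the total of replicate 3, the median of the other 3 libraries, leaving out chromosomes X, Y and M, and removing each library's trend on GC content and exon length (lowess span 0.3) were added after the data were seen; GC content was known for 99.8% of tested genes.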

Results

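Polyadenylated or total RNA of primary T cells from C57BL/6NJ mice, an inbred laboratory strain, was sequenced in 4 libraries that the labels number as biological replicates 1 to 4 of 1 group. The assay is titled total RNA-seq in the labels, while the linked library protocol is named for poly(A)+ RNA, and a protocol for the differentiation of CD4+ T cells is linked as well. The sample labels give no culture condition. The alignment names inside the count files carry the words Th0, activated and 24 h for all 4 libraries. Gene-assigned fragments summed to 60102919 in replicate 1, 273136467 in replicate 2, 48608896 in replicate 3 and 47558517 in replicate 4. Of 50600 annotated genes, 11483 were at 1 TPM or more in all 4 libraries (TPM, an abundance scaled by exon length and library total), 8109 were at 10 or more, and 28329 had no fragment in any library. No second group exists in the labels, so the questions addressed were which gene programmes the cells transcribed, in what order of level, and how far the 4 replicates differed. Gene values below are mean TPM ± SD over the 4 libraries (n = 4).

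Transcripts of the αβ T-cell receptor and of Cd4 were abundant in all 4 libraries. Trac, the constant region of the T-cell receptor α chain (ENSMUSG00000076928.5, mm10 chromosome 14, 54220521 to 54224206), stood at 1676 ± 85.0 TPM. Trbc2, a β-chain constant region, stood at 1009 ± 26.9. Cd4, the co-receptor of helper cells (ENSMUSG00000023274.14, chromosome 6, 124864692 to 124888221), stood at 697 ± 37.9. By contrast Cd8a, the α chain of the cytotoxic-cell co-receptor, was at 0.839 ± 0.0254. Zbtb7b, the regulator that commits thymocytes to the CD4 lineage, was at 91.2 ± 4.35, and Cd40lg, the helper ligand for B cells, at 447 ± 26.7. All 19 members of the list of T-cell receptor complex and proximal signalling genes were at 10 TPM or more in every library, with a list median of 334 TPM. The inhibitory co-receptor gene Cd5 (1002 ± 45.5) and the other β-chain constant region, Trbc1 (727 ± 17.0), were also among its 4 highest members. Cd8b1, the β chain of the CD8 co-receptor, had 46.7 ± 3.55 TPM although Cd8a did not reach 1, and Runx3, a regulator used by CD8+ and by some helper cells, had 60.4 ± 6.41. Of 7 γδ and innate-like T-cell genes, 5 were below 1 TPM in all 4 libraries, and Trdc, the δ-chain constant region, was at 0.785 ± 0.286 TPM.

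Within each library, Cd4 exceeded Cd8a by 8.57 ± 0.09 and Trac exceeded Trdc by 9.89 ± 0.30 on the log2(TPM + 1) scale (mean ± SD, n = 4), each in 4 of 4 libraries. The exact two-sided sign-flip permutation test cannot go below p = 0.13 with 4 libraries, so no pair could pass a threshold of 0.05. That smallest value was reached by 19 of the 25 gene pairs compared (exact permutation p, 0.164 after Benjamini-Hochberg adjustment over the pairs).

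Genes of B cells, myeloid cells, natural killer cells, red cells and stroma were near or below 1 TPM, with a few exceptions. Ighm, the constant region of the IgM heavy chain (ENSMUSG00000076617.9, chromosome 12, 113418558 to 113422730), was at 451 ± 12.7 TPM. Cd79b, which encodes a signalling chain of the B-cell receptor, was at 1.57 ± 0.51. The 5 natural killer genes and the 8 red-cell and platelet genes were below 1 TPM in every library. Among 10 macrophage, monocyte and neutrophil genes, Cd68, a lysosomal glycoprotein, reached 6.44 ± 1.37. Fcer1g came second at 0.711 ± 0.639, and 8 genes of the list were below 1 TPM in every library. Cd74, the chaperone of MHC class II, had 132 ± 6.87 TPM beside 4.33 ± 0.514 for the class II chain gene H2-Ab1. The adhesion gene Pecam1 had 11.0 ± 2.05 beside 1.20 ± 0.364 for the epithelial gene Epcam. Cd3e, the invariant ε chain of the receptor complex, exceeded the macrophage lysozyme gene Lyz2 by 7.58 ± 0.43 and the natural killer receptor gene Ncr1 by 7.73 ± 0.16 on the log2(TPM + 1) scale (mean ± SD, n = 4), in 4 of 4 libraries each.

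Activation genes were high in all libraries. Every member of the 16-gene activation list reached 10 TPM in every library, and the list median was 153 TPM. Tnfrsf4, which encodes the co-stimulatory receptor OX40, had 1300 ± 39.0 TPM, and the transcription factor Irf4 had 827 ± 38.2. Tfrc, the transferrin receptor taken as a sign of growth, had 746 ± 27.5, and Myc, which drives the growth programme, had 665 ± 20.8. Inhibitory receptors that follow activation were abundant too. Pdcd1, encoding PD-1, stood at 407 ± 25.2, Btla at 339.5 ± 9.32, Lag3 at 266 ± 15.1 and Ctla4 at 234 ± 21.9. Havcr2, encoding TIM-3, was below 1 TPM. Genes of resting cells were present as well, unevenly. Tcf7, a regulator of naive and memory cells, stood at 620 ± 14.4, and the lymph-node homing receptor gene Ccr7 stood at 605 ± 15.1. Dgka stood at 124 ± 8.06 and Bach2 at 124 ± 8.30.

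Il2 and lymphotoxin and tumour necrosis factor genes were the highest cytokine transcripts, and the signature cytokines of the Th1, Th2 and Th17 subsets were near or below 1 TPM. Il2, the T-cell growth factor (ENSMUSG00000027720.7, chromosome 3, 37120523 to 37125959), had 1276 ± 71.8 TPM. Lta, encoding lymphotoxin α, had 600 ± 9.93, Tnf had 407 ± 9.93, and Tnfsf11, encoding RANKL, had 372 ± 23.6. Il3 was at 143 ± 9.92 and Csf2 at 8.73 ± 0.970. Of the 21 cytokine genes, 8 were at 10 TPM or more in every library and 10 were below 1 TPM in every library, among them Il4, Il5, Il9, Il10, Il13, Il17a and Il21. Il17a, with 2 fragments over the 4 libraries, and Il4, with 39, were close to the detection limit. No fragment of Il22 or Il6 was counted in any library, which at 3 fragments in the shallowest library allows up to 0.193 TPM of Il22 and 0.0881 TPM of Il6. Ifng, the Th1 cytokine, was at 1.48, 0.215, 0.492 and 0.110 TPM in replicates 1 to 4. The chemokine genes Ccl4 (1417 ± 82.0) and Ccl3 (468 ± 36.8) were high, and the receptor gene Ccr8 was at 143 ± 4.33.

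**Figure D1:**
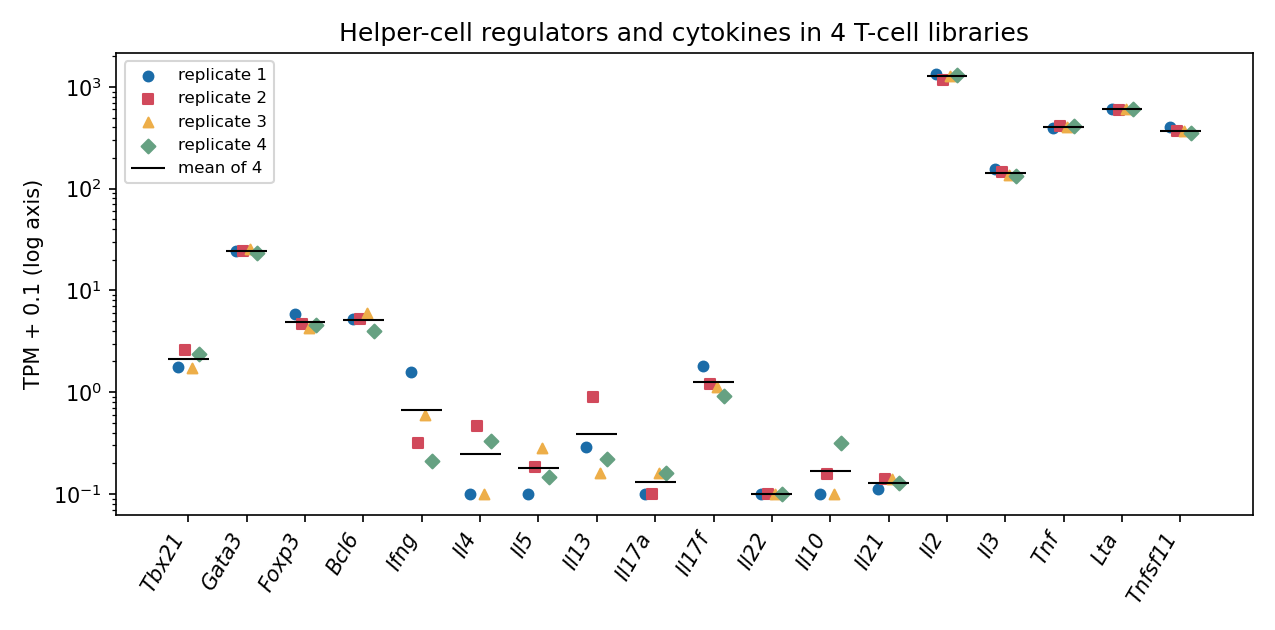
TPM plus 0.1 (log axis) of 4 helper-subset regulators and 14 cytokine genes on the horizontal axis, with a point for each of the 4 libraries and a black line at their mean. Gata3 lies above Foxp3, Bcl6 and Tbx21, and Il2, Lta, Tnf, Tnfsf11 and Il3 lie above 100 TPM while Il4, Il17a and Il22 lie near the detection limit.

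Among the regulators of helper subsets reported here, Gata3 was above the others. Gata3, the regulator of Th2 cells, had 24.3 ± 0.917 TPM. Bcl6, that of follicular helper cells, had 5.01 ± 0.817, Foxp3, that of regulatory T cells, had 4.77 ± 0.718, and Tbx21, that of Th1 cells, had 2.01 ± 0.435. Gata3 exceeded Foxp3 by 2.14 ± 0.18 and Bcl6 by 2.09 ± 0.15 on the log2(TPM + 1) scale (mean ± SD, n = 4), in 4 of 4 libraries each. Foxp3 and Bcl6 differed by -0.06 ± 0.27 (mean ± SD, n = 4), less than the spread between libraries (exact sign-flip permutation p = 0.875). The order of that last pair rested on replicate 3, without which the difference was 0.062.

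Signalling and receptor genes of the helper programmes were present without most of the effector genes. In the Th17 list Stat3 had 59.2 ± 3.05 TPM, the chemokine receptor gene Ccr6 had 41.7 ± 4.41 and Ahr had 22.3 ± 2.25. Il17f had 1.16 ± 0.382 TPM and no fragment of the receptor gene Il23r was counted. In the Th2 list the signalling genes Stat6 (278 ± 15.1) and Il4ra (99.8 ± 9.12) and the receptor genes Ccr8 and Ccr4 (52.4 ± 4.98) were present beside Gata3. The other 4 members, 3 of them cytokine genes, were below 1 TPM in every library. In the Th1 list Il12rb1, a shared chain of the receptors for IL-12 and IL-23, had 119 ± 5.07 TPM and Stat4 had 27.1 ± 0.506. Il12rb2, the chain specific to IL-12, had 3.90 ± 1.17 and Cxcr3 1.79 ± 0.334. Members of the regulatory T-cell list that activated cells also use were the highest, with Tnfrsf18 at 401 ± 29.3, Il2ra at 296 ± 11.0 and Ctla4 as given above. Ikzf2 was at 1.41 ± 0.489. In the follicular helper list Icos had 103 ± 3.31, Sh2d1a 44.3 ± 4.52 and Cxcr5 5.80 ± 0.679 TPM. Cytotoxic genes were low apart from Fasl (30.4 ± 0.751) and Nkg7 (16.2 ± 1.82), with Gzmb at 2.58 ± 0.475 and Prf1 at 0.709 ± 0.174.

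Genes of growth and division were abundant in every library. All 20 S-phase genes and all 20 genes of G2 and mitosis were at 10 TPM or more in every library, with list medians of 224 and 118 TPM. Pcna, the clamp of the DNA polymerases, had 859 ± 38.6 TPM, the helicase subunit gene Mcm3 811 ± 42.3, Mcm5 764 ± 48.9 and Rrm2, a subunit of ribonucleotide reductase, 725 ± 11.4. Top2a had 347 ± 12.7, Ccna2 261 ± 17.7 and Mki67 245 ± 14.6. All 17 glycolysis genes passed 10 TPM in every library, led by Ldha, encoding lactate dehydrogenase (3054 ± 114), Pkm (1772 ± 128), Gapdh (1430 ± 79.7) and Aldoa (1337 ± 94.9). All 13 cholesterol synthesis genes did so too, with Srebf2, the regulator of the pathway, at 336 ± 21.6 and Hmgcs1 at 178 ± 6.78. The translation factor gene Eef1a1 had 9863 ± 342 TPM, the chaperone gene Hsp90ab1 7766 ± 247, Actb 7222 ± 253 and Eef2 6763 ± 470. The 99 ribosomal protein genes had a median of 734 TPM.

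**Figure D2:**
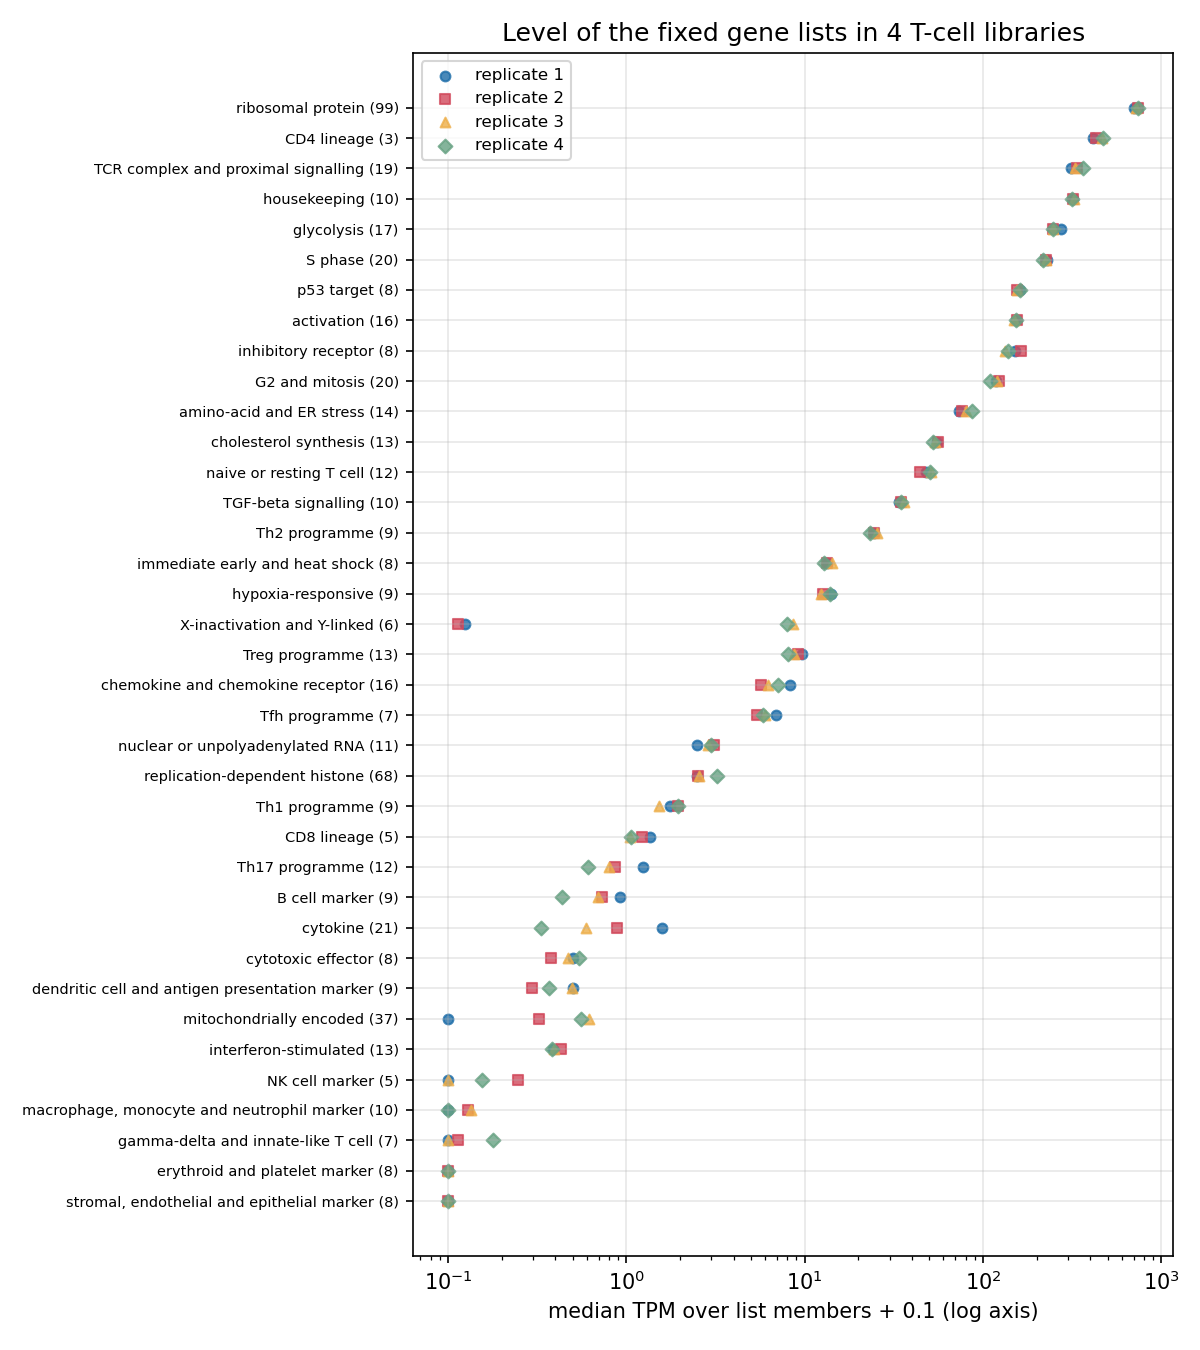
Median TPM over the members of each gene list plus 0.1 (log axis, horizontal) for the 37 lists, with the number of members in parentheses and a symbol for each of the 4 libraries. T-cell receptor, glycolysis and S-phase lists lie above 200 TPM, lists of other cell types lie near or below 1 TPM, and the list of X-inactivation and Y-linked genes is split between replicates.

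The 4 replicates were close for most genes and differed strongly at a few. Pearson's r of log2(TPM + 1) across genes, which are not independent replicates, ran from 0.993 to 0.996 over the 6 pairs of libraries. It covered all annotated genes, including the 28329 without a fragment in any library. For genes at a mean TPM of at least 1, r ran from 0.978 to 0.989. Spearman's rho over all genes ran from 0.915 to 0.922. The edgeR common dispersion corresponded to a biological coefficient of variation of 10.1%. Of 12712 genes tested, 46 varied between replicates beyond other genes of their level (edgeR goodness of fit of an intercept-only model, Benjamini-Hochberg adjusted p under 0.05). Xist, the RNA that silences an X chromosome, had the largest residual deviance, 2625, with 163, 150, 0.715 and 0.696 TPM in replicates 1 to 4. The Y-linked genes Ddx3y (0.0434, 0.0219, 38.8 and 39.3 TPM) and Eif2s3y (0.0677, 0.0364, 41.6 and 38.6 TPM) showed the opposite order. Neither was tested, because the filter asks for a minimum level in all 4 libraries. Genes nearly without fragments in some libraries therefore cannot be among the 46. The labels record sex as not collected. Alpl, the tissue-nonspecific alkaline phosphatase (ENSMUSG00000028766.10, chromosome 4, 137741733 to 137796384), came next with 13.4, 60.9, 14.4 and 67.1 TPM (edgeR adjusted p = 3.0e-86). Mid1, an X-linked ubiquitin ligase gene, had 12.4, 22.5, 8.46 and 1.88 TPM (edgeR adjusted p = 2.1e-64). Bin2, a membrane-curvature protein of blood cells, had 106, 213, 120 and 212 TPM (edgeR adjusted p = 6.3e-22).

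The predicted genes Gm42418, Gm23935 and Gm24187 were lowest in replicate 2, at 1124, 3612 and 836 TPM against 2191 to 4158, 6815 to 8050 and 1652 to 2237 in the other libraries. Gm23935 and Gm24187 have only 57 bases of exon, so their TPM cannot be set against that of longer genes. Gm43305, Gm47283 and Gm42047 completed the 10 genes of largest deviance. List members past the threshold besides Xist were the nuclear RNA Malat1 (highest in replicate 3, 72.3 TPM), the stress gene Sesn2 (82.0 to 115 TPM), the histone gene Hist1h3c (highest in replicate 1, 95.3 TPM) and the mitochondrial ribosomal RNA mt-Rnr1 (highest in replicate 1, 410 TPM). No tested member of the T-cell receptor, activation, cytokine, S-phase, glycolysis or helper-programme lists was past it. Without replicate 2, the deepest library, 25 genes passed, all of them among the 46, and Gm23935, Gm24187, Gm47283 and Sesn2 did not. The calls of Malat1 without replicate 3, of Hist1h3c without replicate 1, of mt-Rnr1 without replicate 1 or 3, with a common dispersion or with GC and length trends removed, and of Sesn2 without replicate 3 or 4, without the filter or with a common dispersion also ended.

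**Figure D3:**
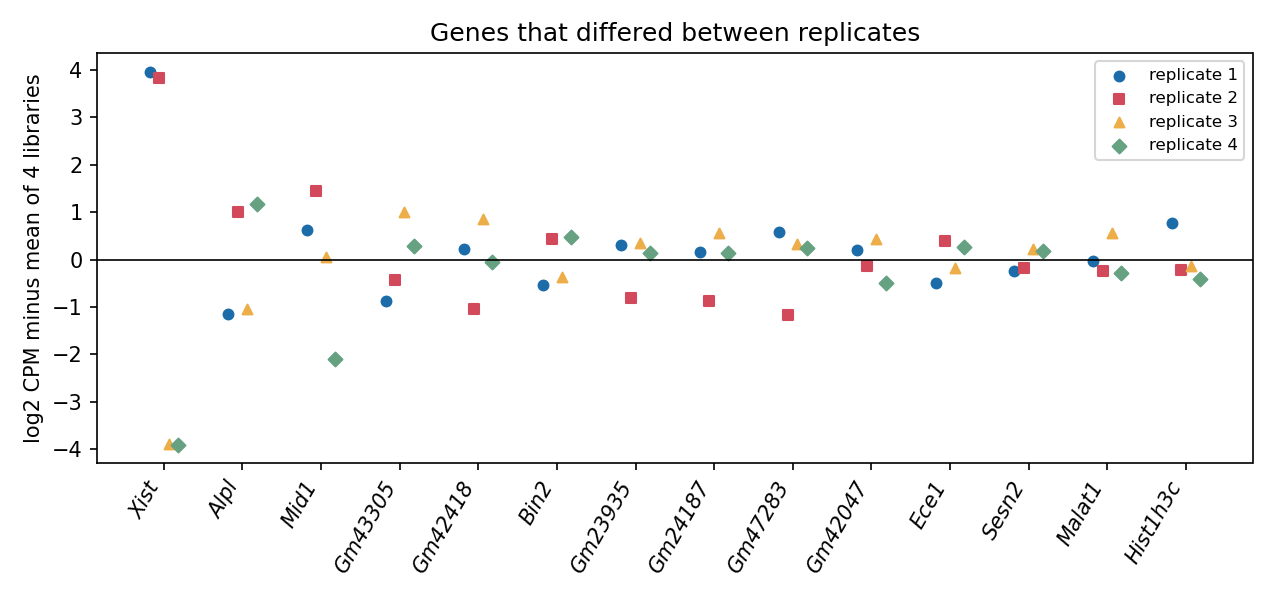
Difference of log2 CPM from the mean of the 4 libraries (vertical axis) for the 10 genes of largest residual deviance and for Ece1, Sesn2, Malat1 and Hist1h3c, with a symbol for each library. Replicates 1 and 2 lie about 3.96 and 3.82 above the mean for Xist and replicates 3 and 4 lie below it, while replicates 2 and 4 lie above the mean for Alpl, Bin2 and Ece1.

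The spread between replicates was placed among random lists for 28 gene lists, as a description. No difference between lists was tested. Of 100 random lists used as a check, 5 fell above percentile 95. Ribosomal protein genes had a median residual deviance of 2.38 over 96 genes, above 100% of 10000 random lists matched on level. The random lists draw genes singly, so a list whose members move together reaches extreme percentiles more easily. Of the 96 genes 0 were past the threshold for variation. The follicular helper list (5.67 over 5 genes), the p53 target list (3.71 over 7 genes) and the Th17 list (4.42 over 7 genes) were at percentiles 98.6, 98.4 and 95.1. S-phase genes were among the least variable, with a median deviance of 0.815 over 20 genes at percentile 6.03. With single libraries left out the percentile of the follicular helper list fell to 61.5 without replicate 2, 76.4 without replicate 3 and 80.8 without replicate 4. That of the Th17 list fell to 69.7 without replicate 4 and 92.0 without replicate 2, that of the p53 list to 93.7 without replicate 2 and that of ribosomal protein genes to 94.6 without replicate 4.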

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

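Among 194 sets of 4 library values, 9 had a library whose gap to its nearest neighbour was too large a share of the whole range for 4 samples; chance gives about 1 in 20 such sets. Replicate 2 stood apart in depth, with 273136467 fragments against 47558517 to 60102919. The inhibitory receptor list was highest in replicate 2, with a mean log2 deviation of 0.0898 against -0.0394 to -0.0221 in the other libraries, and Stat4, the signal transducer of IL-12, was lowest there, at 26.3 TPM against 27.3 to 27.4. The other 6 sets set replicate 1 apart, each time on the low side. Stat6 was at 255 TPM in replicate 1 against 284 to 287, Stat3 at 54.7 against 60.3 to 61.2, Mcm3 at 748 against 829 to 834, the glycolytic gene Pkm at 1582 against 1814 to 1861, the hypoxia-responsive gene Ankrd37 at 14.8 against 17.7 to 18.1, and Tubb5, a β-tubulin, at 3485 against 3678 to 3706. None of these 7 genes was past the threshold for variation between replicates in the edgeR test. Replicate 1 also had the strongest trend of gene deviations on GC content across genes, with Spearman's rho of -0.343 against 0.080, 0.190 and 0.200 in replicates 2, 3 and 4.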

How the results depend on the processing

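Thinning replicate 2, removing GC and length trends and leaving out chromosomes X, Y and M were chosen after the data were seen. The number of genes at 1 TPM in all libraries (11483) stayed between 9892 and 12786 under its 9 alternatives. The lowest Pearson's r (0.9926) moved to 0.9826 with a pseudocount of 0.1, 0.9782 for genes at a mean TPM of at least 1 and 0.9926 to 0.9942 with each replicate left out. The biological coefficient of variation moved to 16.2% without the filter, which admits genes of few counts, and ran from 8.71% (without replicate 1) to 11.0% with a replicate left out. The 46 variable genes became 862 with a common dispersion, 25 (without replicate 2) to 40 with a replicate left out, and 42 to 57 under the other alternatives; similar counts were not always the same genes. Of the 46 genes 31 were shared without the filter (46 called), 35 with a mean of at least 50 counts (54 called), 35 with a common dispersion, 29 without replicate 1 (40 called), 42 of 57 with trends removed and 42 of 42 with replicate 2 thinned. Of 175 alternatives for gene pairs 173 kept the direction; Foxp3 minus Bcl6 ran from -0.129 to 0.062 (without replicate 3) and Il17a minus Il10 from -0.093 to 0.001 (without replicate 4). Of 257 alternatives for list levels 247 stayed within 1.5 times. At 0.5 TPM in all libraries 4 CD8 lineage genes, 4 B-cell, 2 stromal and 1 X-inactivation or Y-linked gene passed, and at 1 FPKM 0 γδ, 2 Th1, 2 interferon-stimulated, 1 B-cell and 4 nuclear RNA genes; without single replicates the stromal list had 1 to 2. Of 168 alternatives for list spread 152 stayed on their side of percentile 95. With a mean of at least 50 counts the Th17 list was at 85.6 and the follicular helper list at 93.0. With each replicate left out the percentile ran from 69.7 to 98.6 for Th17, 72.9 to 98.8 for regulatory, 61.5 to 99.9 for follicular helper, 3.88 to 99.9 for resting T-cell, 6.30 to 100 for mitosis, 32.0 to 97.9 for glycolysis, 93.75 to 99.99 for p53, 63.9 to 97.4 for B-cell, 63.8 to 98.5 for nuclear RNA and 94.6 to 100 for ribosomal protein genes. The cause was not tested for these changes, and 3 libraries leave fewer samples. Depth limits statements on cytokine genes with few fragments.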

Other observations

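The tests of explanations in this part were all chosen after the patterns were seen. Genes of several stress and signalling lists not described above were transcribed. Without a second group these levels cannot show whether a stress response was under way. The amino-acid and ER stress list had a median of 81.0 TPM, with Atf4, the regulator of the amino-acid response, at 767 ± 15.1 TPM (mean ± SD, n = 4), the ER chaperone gene Hspa5 at 694 ± 30.9 and the serine synthesis genes Phgdh at 475 ± 37.3 and Psat1 at 341 ± 7.79. Targets of p53 had a median of 158 TPM, with Ccng1 at 465 ± 31.6, the cell-cycle inhibitor gene Cdkn1a at 434 ± 46.7 and Bax, a mediator of apoptosis, at 431 ± 30.1. Of 13 interferon-stimulated genes 8 were below 1 TPM in every library, while Bst2 had 233 ± 4.27 TPM. Among immediate early and heat shock genes Junb was at 538 ± 26.3 and Hsph1 at 198 ± 11.2, and in the TGF-β list Ski was at 88.2 ± 4.65 and Smad2 at 74.7 ± 3.06. Hypoxia-responsive genes were modest, with P4ha1 at 59.0 ± 1.81 and Pdk1 at 46.8 ± 0.567. Mitochondrially encoded genes, led by mt-Co1 (5016 ± 205 TPM), took 0.580% to 0.612% of the counts, and of the nuclear or unpolyadenylated RNAs Gas5 was at 210 ± 12.3 and Rpph1 at 169 ± 25.4.

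Ighm was at 433 to 462 TPM in the 4 libraries without other B-cell transcripts at a like level. B cells or plasma cells would bring their other abundant transcripts; the highest of Cd79a, Cd79b, Ms4a1 and Igkc in any library was 2.42% of Ighm, which argues against such cells as the source, although 2 of the 9 B-cell list genes, Ighm and Cd79b, were at 1 TPM or more in every library. No annotated gene overlapped Ighm on its strand, and the highest of the 5 same-strand neighbours within 5 kb was at 2.16% of Ighm, which argues against fragments of annotated neighbours. Transcription of the constant region in the T cells themselves may remain as a hypothesis, and the counts per gene cannot show which exons were covered. No biological explanation was tested.

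Alpl and its neighbour Ece1, which encodes an endothelin-converting enzyme (chromosome 4, 137862237 to 137965229), deviated from their means with the same sign in each of the 4 libraries, Ece1 with 29.3, 55.6, 36.9 and 49.8 TPM in replicates 1 to 4 (edgeR adjusted p = 1.7e-09). GC content and length bias is argued against, since 90.7% or more of the log2 range of both genes was left after each library's trends were removed. Variation local to the chromosome, such as a variant that segregates between animals, could move neighbours together, and 8 of the 38 variable autosomal genes had another within 1 Mb, against a mean of 2.55 in 10000 random draws matched on level (permutation p = 0.0277). Alpl and Ece1 were then left out, and genes closer than 10 kb were not counted as neighbours. Of 36 genes 4 then had a neighbour, against a mean of 2.28 (permutation p = 0.306). The random draws count closeness only, not shared direction. In the pairs left, Ubxn11 and Hmgn2 had opposite signs in every library, and Stra6 and Cyp1a1 in replicates 1, 2 and 4. Of the 14 tested genes within 1 Mb of Alpl, only 1, Ece1, was past the threshold. Local variation stays open, and the counts hold no genotype. Signs shared with Alpl do not decide the question, since these genes were picked after their values were seen. Bin2 on chromosome 15 had the same signs as Alpl. Ubxn11 and Prdm16 on chromosome 4, farther than 1 Mb from Alpl, also had them. For Prdm16 the log2 deviations in replicates 2 and 3 were small (0.022 and -0.059). Hmgn2, beside Ubxn11, deviated with the opposite signs. The other variable genes of chromosome 4 shared the signs of Alpl in part. Dhrs3 did so in all but replicate 3, Gm11223 in all but replicate 4, and Sesn2 in replicates 1 and 4 only.

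Replication-dependent histone genes had a median of 2.42 TPM beside 224 TPM for the S-phase list. Selection of polyadenylated RNA would remove these transcripts, which lack a tail, and is consistent with the histone variant genes H2afz, H2afx, H2afv, H2afj, H2afy, H3f3a and H3f3b having a median at least 58.4 times as high in every library, and with a median of 1.60 TPM over 6 small RNAs without a tail, although Rpph1 among these was at 169 TPM. Loss of fragments shared between near-identical histone copies as the main cause is argued against, since the 6 linker histone H1 genes, which differ more in sequence, were at most 3.51 times as high as the core histone genes in any library. How many cells were in S phase was not measured, and no biological explanation was tested.

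Besides Xist, the X-linked genes Kdm6a (31.0, 32.4, 20.5 and 18.9 TPM in replicates 1 to 4), Eif2s3x (149, 141, 92.9 and 96.7 TPM), Pbdc1 (46.2, 46.7, 33.8 and 31.1 TPM) and Kdm5c (168, 189, 131 and 125 TPM) and, as given above, Mid1 were past the threshold for variation in the edgeR test. All of these genes were higher in replicates 1 and 2 than in replicates 3 and 4, as Xist was. Mid1 also differed within these pairs, with 12.4 and 22.5 TPM in replicates 1 and 2 and 8.46 and 1.88 TPM in replicates 3 and 4. The calls of Kdm5c without replicate 2, 3 or 4 and of Pbdc1 without replicate 2 or 4, and of both with a common dispersion, ended. Of the 46 variable genes 8 lay on chromosome 4, where 2.81 would match its share of tested genes (776 tested). On the X chromosome 6 lay, Xist among them, against 1.53 by its share (424 tested). All 6 were higher in replicates 1 and 2, the libraries nearly without fragments of the Y-linked genes Ddx3y and Eif2s3y. The X-linked calls thus go with that split and are not 6 unrelated cases of spread. Chromosomes 4 and X were in excess by a narrow margin over the 22 chromosomes tested (Fisher's exact adjusted p = 0.0450 and 0.0442). The only tested gene on chromosome Y, Gm47283, was also past the threshold (Fisher's exact adjusted p = 0.0442). The test takes genes as independent, although neighbours such as Alpl and Ece1 were both counted. These counts rest on calls of which several ended under alternatives. Cd8b1 had 5560 fragments in replicate 2, where Cd8a had 248.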
